A study of Mus musculus with 6 samples.

How the data were processed

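SMAD1/5-bound chromatin was immunoprecipitated with an anti-Smad1 antibody from formaldehyde-fixed cells, sonicated and sequenced, per the labels' protocols. The series has 6 groups, each of 1 library: 2 input DNA libraries, which were not analysed here, and 4 immunoprecipitated libraries. The labels place each library in its group through its title. The submitters' processing notes name Bowtie 1.1.0, Picard and MACS 1.4.2 on the mm9 build, without saying which step used which tool. The read filters, the duplicate treatment, the library that served as control for each list and the number of reads are not given in the sources used here.

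The authors deposited 1 peak list per immunoprecipitated library, in 5 columns without a header: chromosome, start, end, peak name and a score per peak. The deposited score is the authors' own value for each peak, and its scale is not given in the sources used here. By MACS convention it would be minus 10 times the log10 of a p-value. The lowest score was 50.0 to 50.2 in each list. The score was used only to rank or filter peaks within its own list, because it depends on depth and on the control. Depth per library is unknown, so the precision of a peak's presence or absence cannot be given, and a place missing from a list is not a place without binding. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals over peaks. They cover counting error only, and peaks of 1 library are neither independent nor replicates.

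Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Counts differ by direction because 1 wide peak can meet several narrow ones. Regions were made by merging overlapping or touching peaks of the lists compared. Chance overlap was taken from 1000 seeded placements of each peak, with its own width, at a random position of its own chromosome. The end points of each chromosome were the first and last peak position over the 4 lists, since no mm9 chromosome lengths were used, and sequence gaps were not excluded. A second placement kept peaks within 50 kb of a peak: of either ESC list when the ESC lists were compared, and of any of the 4 lists when ESD-EpiSC peaks were set against ESCs. The difference in score between shared and unshared peaks was given as the probability that a shared peak scores higher, with ties counted equally for both, and a bootstrap interval from 1000 resamples of peaks. Positions are printed 1-based.

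The interval code was tested on simulated data with the real peak widths. For LIF+serum peaks against LIF+BMP-4 peaks (9387 peaks), lists made to share 60.3% gave 60.3%. For 1.5 h peaks against LIF+BMP-4 peaks (225 peaks), lists made to share 30.2% gave 30.2%, and the bootstrap interval of the score probability held the true value in 94% of simulated sets.

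The main comparisons with their tests, and most alternatives, were fixed before the data were examined. The alternatives fixed then were a score of at least 100, overlap of at least 50% of the shorter peak, extension of peaks by 1 kb, lists of equal length (each longer list reduced to its highest-scoring peaks, as many as the shortest list of that comparison held), removal of unplaced sequences, chromosome Y and peaks over 5 kb, comparison within tertiles of peak width, and placement near peaks. Removal of ESD-EpiSC peaks of 80 bp or less and of chromosomes 8, X and Y was added after the data were seen, as were the examination of single chromosomes, narrow peaks and dense windows and the tests that the closing section names as chosen afterwards. The named positions follow a rule set beforehand for the case that no mm9 annotation is at hand: the 5 highest-scoring peaks of each list and every region with a peak in all 4 lists. The gene table at hand belongs to GRCm38.p6 and was not used, because positions of different builds cannot be set against each other. Promoter shares, the fixed lists of BMP target, pluripotency and lineage genes, and the motif search were therefore not run.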

Results

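SMAD1/5 binding was mapped by ChIP-seq in mouse E14 embryonic stem cells (ESCs, the naive pluripotent state) and in epiblast stem cells derived from them (ESD-EpiSCs, the primed state). SMAD1 and SMAD5 are the transcription factors that bone morphogenetic protein (BMP) receptors activate. Peak lists from 4 immunoprecipitated libraries were analysed: ESCs kept in LIF+serum, ESCs kept in LIF+BMP-4, and ESD-EpiSCs given BMP-4 for 1.5 h or for 24 h. BMP-4 was used at 10 ng/ml. Each condition was 1 library with no replicate, so no difference between conditions has a replicate check, and no p-value is given. The library titles name LIF for ESCs only and timed BMP-4 for ESD-EpiSCs only. Naive against primed state therefore cannot be told apart from culture, BMP-4 exposure or library. The lists hold peaks and not reads, so the sequencing depth behind them is unknown. All positions are mm9 and are given without gene names, because no mm9 annotation was used here.

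The first question was how widely SMAD1/5 was detected in each state. The ESC lists held far more peaks than the ESD-EpiSC lists. There were 9387 peaks in LIF+serum and 14696 in LIF+BMP-4, against 225 after 1.5 h and 133 after 24 h of BMP-4 in ESD-EpiSCs. The LIF+serum peaks covered 8.11 Mb with a median width of 811 bp, and the LIF+BMP-4 peaks covered 7.85 Mb with a median width of 500 bp. Although the LIF+BMP-4 list was 1.57 times as long, the LIF+serum list covered 1.03 times as much sequence. The ESD-EpiSC peaks covered 37.9 kb at 1.5 h and 15.6 kb at 24 h, with median widths of 123 bp and 102 bp. The median score was 70.5 in LIF+serum, 76.4 in LIF+BMP-4, 61.4 at 1.5 h and 59.5 at 24 h, from a lowest score of 50.0 to 50.2 in each list. A score of at least 100 was reached by 2165 LIF+serum peaks, 4372 LIF+BMP-4 peaks, 44 peaks at 1.5 h and 10 peaks at 24 h. List length depends on depth and on the input control, so these counts describe the calls and do not measure occupancy. Scores rank peaks within a list and are not a measure between lists.

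The second comparison asked whether ESCs in serum and in defined BMP-4 medium carried SMAD1/5 at the same places. Of the LIF+serum peaks, 5517 of 9387 (58.8%, exact binomial 95% interval 57.8 to 59.8) overlapped a LIF+BMP-4 peak. Of the LIF+BMP-4 peaks, 5683 of 14696 (38.7%, 37.9 to 39.5) overlapped a LIF+serum peak. Merging both lists gave 18386 regions, of which 5503 (29.9%) had a peak in both media, 3870 in LIF+serum only and 9013 (49.0%) in LIF+BMP-4 only. Random placement of the LIF+serum peaks on their own chromosomes gave a mean of 80.4 overlaps and a maximum of 108 in 1000 placements, so the observed count was 68.6 times the mean. Placement restricted to within 50 kb of a peak of either ESC list lowered that ratio to 25.8.

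Peaks found in both media tended to score higher within each list. In LIF+serum the median score was 81.35 for shared peaks and 61.86 for the others, and a shared peak outscored an unshared one with probability 0.71 (bootstrap 95% interval 0.70 to 0.72). In LIF+BMP-4 the medians were 104.07 and 67.27, with a probability of 0.75 (0.74 to 0.76). Shared peaks were also wider, and within tertiles of peak width the probabilities were 0.672 in LIF+serum and 0.699 in LIF+BMP-4. The share of LIF+serum peaks also called in LIF+BMP-4 was 39.0% (36.8 to 41.3) in the lowest quintile of scores and 88.3% (86.8 to 89.8) in the highest. The corresponding shares of LIF+BMP-4 peaks were 17.2% (15.9 to 18.6) and 77.1% (75.6 to 78.6). The intervals cover counting error over peaks of a single library only.

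**Figure D1:**
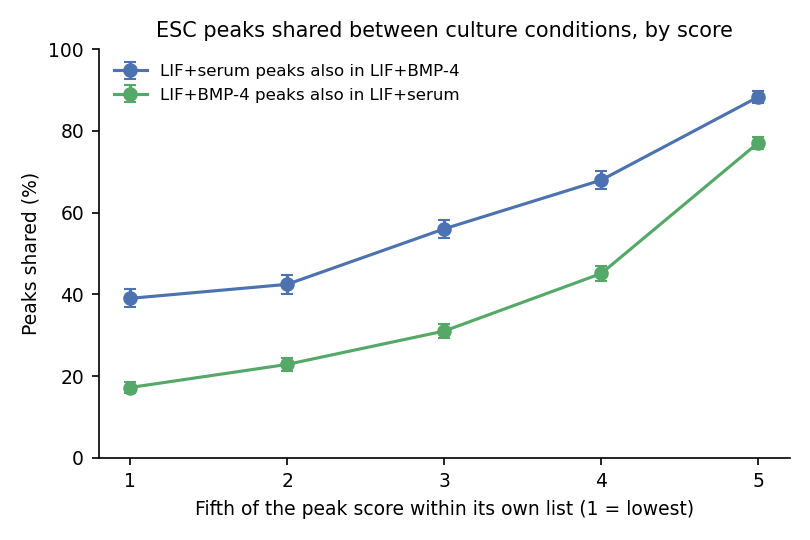
Share of ESC peaks (%, y axis) that overlapped a peak of the other ESC list, by quintile of the score within its own list (x axis, 1 is the lowest); points are shares and bars are exact binomial 95% intervals. LIF+serum shares go from 39.0% to 88.3% and LIF+BMP-4 shares from 17.2% to 77.1%.

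The strongest ESC sites were held in common. All 5 top-scoring LIF+serum peaks and all 5 top-scoring LIF+BMP-4 peaks had a counterpart in the other medium. The highest peak of both lists lay on chromosome 11 at 115302512 to 115303463 in LIF+serum (score 1331.51) and at 115302505 to 115303380 in LIF+BMP-4 (score 2169.55). A peak on chromosome 8 at 24013030 to 24014258 ranked 3 in both lists. A peak on chromosome 10 at 92933863 to 92934933 ranked 4 in LIF+serum and 5 in LIF+BMP-4. The peak on chromosome 11 at 97084354 to 97085681 ranked 2 in LIF+serum and 84 in LIF+BMP-4, and the peak on chromosome 8 at 11608053 to 11610562 ranked 5 and 23. Conversely, the peak on chromosome X at 166420916 to 166424182 ranked 2 in LIF+BMP-4 and 152 in LIF+serum, and that on chromosome 7 at 135010920 to 135011795 ranked 4 and 8. Among 5330 pairs of peaks that overlapped each other and no other peak, the midpoints lay a median of 70.5 bp apart, and 89.8% lay within 200 bp.

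The third comparison set early against late BMP-4 treatment of ESD-EpiSCs. Few places were called at both times: 16 of 225 peaks at 1.5 h (7.11%, 4.12 to 11.3) overlapped a 24 h peak, and 17 of 133 peaks at 24 h (12.8%, 7.63 to 19.7) overlapped a 1.5 h peak. Random placement gave at most 1 overlap in 1000 placements in either direction, with means of 0.005 for 1.5 h peaks and 0.007 for 24 h peaks. For lists this short and narrow a value near 0 was nearly certain. The placements therefore do not test why the 2 times shared places. Merging all 4 lists gave 17 regions with a peak at both times, of which 10 also had a peak in at least 1 ESC list. In the region on chromosome 15 the peaks of the 2 times were joined only through ESC peaks. Of the 17, 5 lay on chromosome 8 and 2 on chromosome X. Those on chromosome X had no ESC peak, nor had those on chromosome 8 at 44492752, 86400388 and 86704415. Without chromosomes 8, X and Y, a setting added after the data were seen, the shares were 9 of 182 (4.95%) at 1.5 h and 10 of 97 (10.3%) at 24 h. Lists of equal length raised the 1.5 h share to 12.0%. Among peaks with a score of at least 100 the shares were 2 of 44 (4.55%) at 1.5 h and 2 of 10 (20.0%) at 24 h, counts too small to place either share closely.

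Most of the 5 highest 1.5 h peaks were not called at 24 h, whereas most of the 5 highest 24 h peaks were also called at 1.5 h. At 1.5 h the top 5 were on chromosome 6 at 72166707 to 72167014 (score 1941.28), chromosome 17 at 39979942 to 39983328 (1081.14), chromosome 7 at 77502650 to 77503219 (646.81), chromosome 10 at 12810517 to 12811119 (382.82) and chromosome 13 at 48323123 to 48323434 (361.77). Of these, 4 had no peak in either ESC list. The exception on chromosome 10 ranked 58 in LIF+serum and 56 in LIF+BMP-4, and the peak on chromosome 13 was the one called again at 24 h (score 94.65). The peak on chromosome 17 was the widest of the 1.5 h list, at 3387 bp against a median of 123 bp. Sequence was not examined, so read pile-up in repeated sequence was not tested there. At 24 h all 5 top peaks also had a peak in both ESC lists. They lay on chromosome 6 at 127286728 to 127287103 (score 384.56), chromosome 10 at 30347350 to 30347716 (263), chromosome 15 at 61924343 to 61924579 (142.14) and 56574379 to 56574561 (141.79), and chromosome 4 at 135696472 to 135696691 (131.67). The peaks on chromosomes 6, 10 and 4 were present at 1.5 h as well.

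The fourth comparison asked how much of the primed-state binding fell on naive-state sites. Of the ESD-EpiSC peaks, 78 of 225 at 1.5 h (34.7%, 28.5 to 41.3) and 36 of 133 at 24 h (27.1%, 19.7 to 35.5) overlapped a peak of either ESC list, while 147 and 97 overlapped none. Most of the overlapping peaks were on sites used in both media: 52 of the 1.5 h peaks hit both ESC lists, 13 hit LIF+serum only and 13 hit LIF+BMP-4 only. At 24 h the numbers were 20, 6 and 10. Random placement gave means of 1.53 overlaps at 1.5 h and 0.823 at 24 h, so the observed counts were 51.1 and 43.7 times those means, or 19.6 and 16.0 times with placement within 50 kb of any peak of the 4 lists. As for the ESC lists, a shared uneven spread along the chromosomes would raise these ratios, so they do not single out shared binding. Among 24 h peaks also called at 1.5 h, 10 of 17 (58.8%, 32.9 to 81.6) were ESC sites, against 26 of 116 (22.4%, 15.2 to 31.1) of those called at 24 h alone. For 1.5 h peaks the shares were 9 of 16 (56.3%, 29.9 to 80.2) and 69 of 209 (33.0%, 26.7 to 39.8), with overlapping intervals. The 10 peaks at 24 h include 2 from a single region on chromosome 4, and neither contrast was matched for peak width. ESC sites that ESD-EpiSCs also carried ranked high in ESCs, with a median score percentile of 84.0 among LIF+serum peaks (69 peaks) and 86.9 among LIF+BMP-4 peaks (76 peaks). Within the ESD-EpiSC lists, the probability that a shared peak scored above an unshared one was 0.55 (0.48 to 0.63) at 1.5 h and 0.61 (0.49 to 0.71) at 24 h, and both intervals held 0.5. Among the highest 24 h peaks sharing was more frequent: 7 of 10 peaks scoring at least 100 (70.0%, 34.8 to 93.3) met an ESC peak, against 29 of 123 below that score (23.6%, 16.4 to 32.1). At 1.5 h the shares were 16 of 44 (36.4%, 22.4 to 52.2) and 62 of 181 (34.3%). With each ESC list reduced to its top peaks, as many as the ESD-EpiSC list compared held, the overlap was 10.2% at 1.5 h (225 peaks per ESC list) and 1.50% at 24 h (133 peaks per ESC list), so these 2 shares do not rest on the same ESC peaks. With only peaks scoring at least 100 in each list, it was 22.7% (10 of 44) and 70.0% (7 of 10, 34.8 to 93.3).

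ESD-EpiSC peaks that were found in ESCs were rarely narrow. Peaks of 80 bp or less numbered 32 at 1.5 h and 39 at 24 h, and there were 0 in either ESC list. That 0 followed from wider ESC peaks throughout. The narrowest ESC peak was 270 bp in LIF+serum and 188 bp in LIF+BMP-4. The third quartile of ESD-EpiSC widths was only 176 bp at 1.5 h and 131 bp at 24 h. Whether a property of the whole library, such as fragment length or caller settings, gave this gap was not tested. Of the narrow peaks, only 2 of 32 (6.25%, 0.766 to 20.8) and 2 of 39 (5.13%, 0.627 to 17.3) overlapped an ESC peak. Among wider peaks, 76 of 193 (39.4%, 32.4 to 46.7) at 1.5 h and 34 of 94 (36.2%, 26.5 to 46.7) at 24 h did. This width limit was chosen after the data were seen. Of the 71 narrow peaks of both times, 17 (23.9%) lay on chromosome X and 0 on chromosome Y, and of the 287 wider ones 2 and 4.

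**Figure D2:**
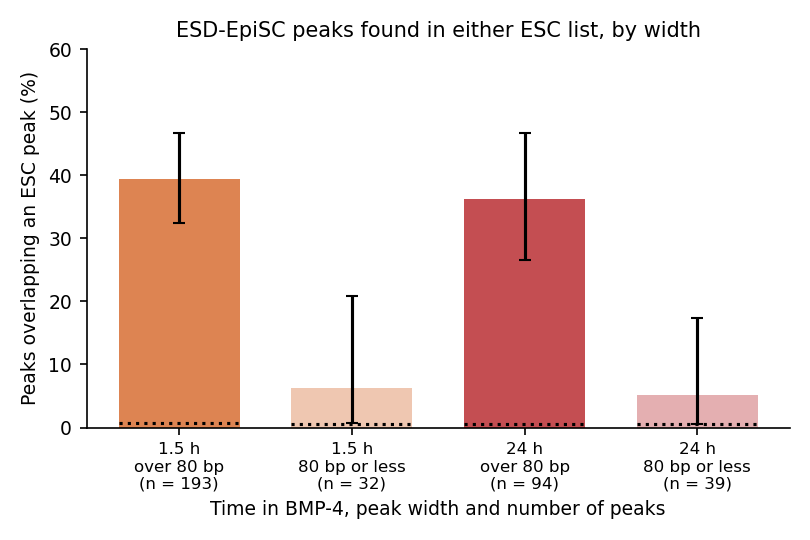
Share of ESD-EpiSC peaks (%, y axis) that overlapped a peak of either ESC list, by time in BMP-4 and peak width (x axis); bars are shares, error bars exact binomial 95% intervals and dotted lines the mean of 1000 random placements. Wider peaks reach 39.4% and 36.2%, and peaks of 80 bp or less 6.25% and 5.13%.

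The last question was which regions all 4 libraries shared. There were 7 of 18623 merged regions with a peak in every list. Separately, 7 of the 24 h peaks overlapped a peak of each of the 3 other lists. Random placement of both ESD-EpiSC lists gave 0 such peaks in each of 1000 placements. Placed 24 h peaks met a 1.5 h peak only 0.007 times on average. A value of 0 was therefore nearly certain and tests no shared core. The 7 peaks are not 1 per region: the chromosome 4 region held 2 peaks at 24 h. In the chromosome 15 region, the 1.5 h and 24 h peaks were joined only through ESC peaks. The region on chromosome 2 at 157384621 to 157386589 ranked 7 in both ESC lists, 15 at 1.5 h and 127 at 24 h. The region on chromosome 6 at 127286387 to 127287562 held the highest 24 h peak and ranked 27 at 1.5 h, 1307 in LIF+serum and 2650 in LIF+BMP-4. The region on chromosome 10 at 30347029 to 30348593 ranked 2 at 24 h and 87 at 1.5 h. On chromosome 4 at 135695966 to 135696983 the ranks were 5 at 24 h, 24 at 1.5 h, 746 in LIF+serum and 12355 in LIF+BMP-4. The others lay on chromosome 8 at 8608805 to 8610003 and at 131178173 to 131179146, and on chromosome 15 at 93351298 to 93352185. A score of at least 100 in every list, or lists of equal length, each left 1 region.

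Within 100 kb of chromosome 2, the calls in naive and primed cells overlapped in part. The interval from 152.5 to 152.6 Mb was singled out after its values were seen. The reason was that it held 3 of the 17 merged regions with an ESD-EpiSC peak at both times. These lay at 152533313 to 152533580, 152560787 to 152561054 and 152565128 to 152565351 at 1.5 h, with ranks 12, 23 and 20, and ranked 93, 66 and 44 at 24 h. The first met a LIF+BMP-4 peak of rank 14333, the second met a LIF+serum peak of rank 6344, and the last met no ESC peak. The strongest ESC peak of the interval, at 152511983 to 152513228 in LIF+serum (rank 96) and at 152512275 to 152513098 in LIF+BMP-4 (rank 46), met no ESD-EpiSC peak. With unknown depth, a missing call there does not show missing binding.

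**Figure D3:**
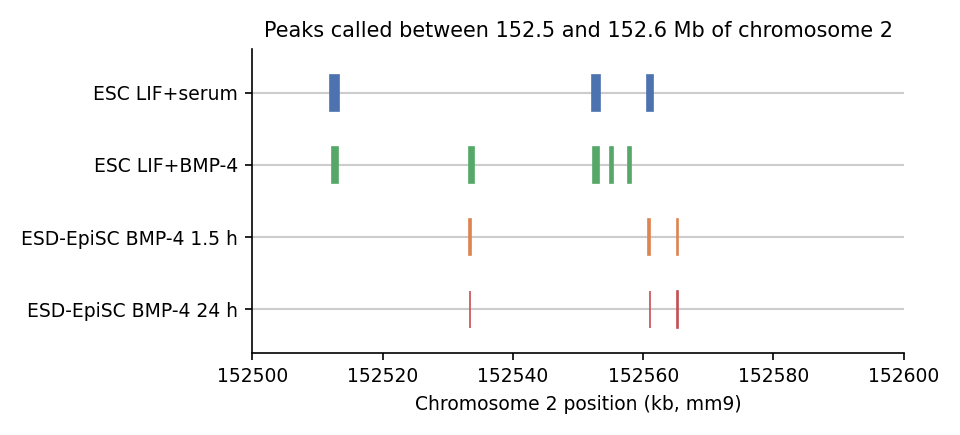
Peaks of each list (one line per library) along chromosome 2 between 152.5 and 152.6 Mb (x axis, position in kb, mm9); each box is a peak drawn to scale, with a thin outline that keeps the narrowest ones visible. The 3 ESD-EpiSC places appear at both 1.5 h and 24 h, and the leftmost ESC peak, at 152511983 to 152513228 in LIF+serum, has no ESD-EpiSC peak.

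The spread of peaks over chromosomes also differed between the lists. Chromosome 8 held 7.00% (6.49 to 7.53) of LIF+serum peaks and 7.62% (7.20 to 8.06) of LIF+BMP-4 peaks, against 34 of 225 peaks at 1.5 h (15.1%, 10.7 to 20.5) and 22 of 133 at 24 h (16.5%, 10.7 to 24.0). Chromosome X held 0.746% of LIF+serum and 0.905% of LIF+BMP-4 peaks, against 9 peaks (4.0%, 1.85 to 7.46) at 1.5 h and 10 peaks (7.52%, 3.66 to 13.4) at 24 h. By the span from first to last peak, chromosome 8 was 5.01% and chromosome X 6.28% of all chromosomes. All 4 chromosome 8 shares lay above its span share. On chromosome X both ESD-EpiSC intervals held the span share, and the ESC shares lay below it. Without peaks of 80 bp or less, 1 peak remained on chromosome X at each time, and the chromosome 8 share was 15.0% (10.3 to 20.9) at 1.5 h and 9.57% (4.47 to 17.4) at 24 h. A single cluster on chromosome 8, from 19720076 to 20019922, held 6 of the 34 peaks at 1.5 h and 8 of the 22 at 24 h; outside it the shares were 12.8% (8.67 to 17.9) and 11.2% (6.26 to 18.1). Chromosome Y held 4 peaks at 24 h (3.01%, 0.825 to 7.52), all wider than 80 bp, and 0 at 1.5 h, 1 in LIF+serum and 0 in LIF+BMP-4. These chromosomes and the cluster were singled out after the data were seen.

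**Figure D4:**
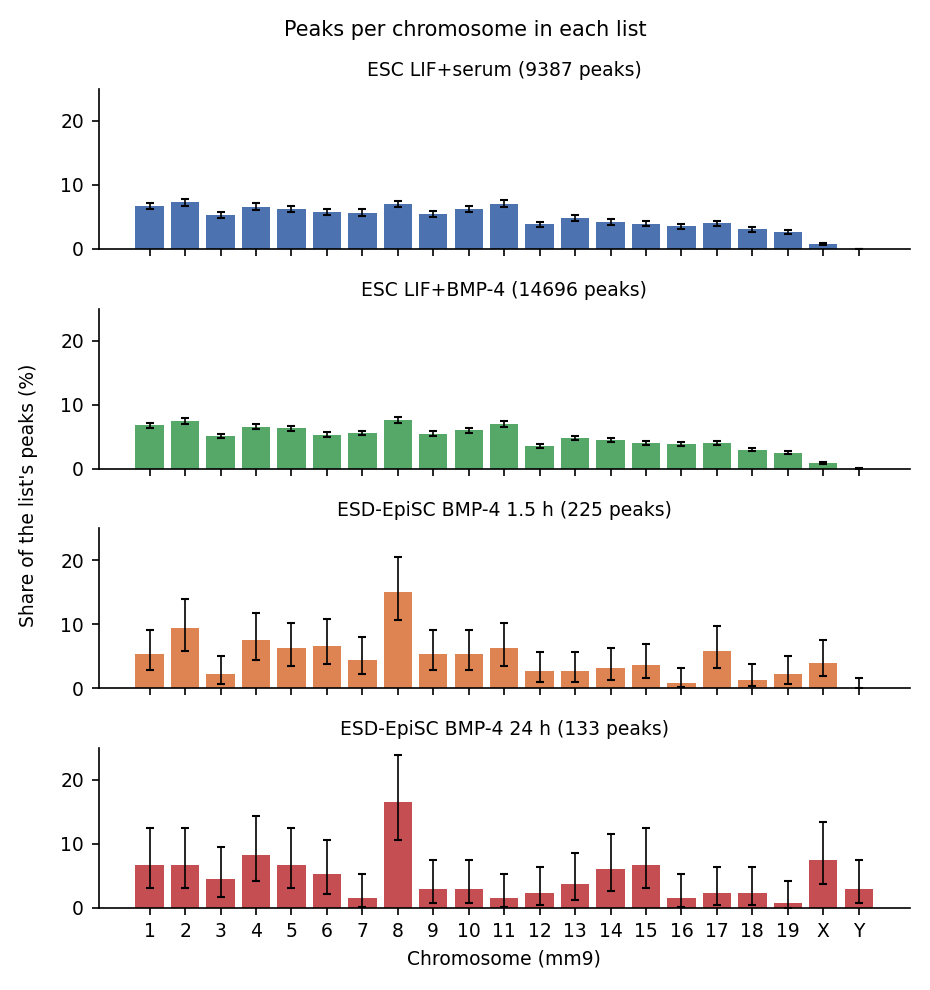
Share of each list's peaks (%, y axis) on each mm9 chromosome (x axis), one panel per library; bars are shares and error bars exact binomial 95% intervals. Chromosome 8 holds 15.1% and 16.5% of the ESD-EpiSC peaks at 1.5 h and 24 h, and 7.00% and 7.62% of the ESC peaks.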

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

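Of the planned settings, those that need an mm9 annotation or sequence (promoter share, gene lists, motifs) were not run. No paired analysis was possible because each condition has 1 library. A score of at least 100 left 2165 LIF+serum, 4372 LIF+BMP-4, 44 (1.5 h) and 10 (24 h) peaks. It moved the share of LIF+serum peaks in LIF+BMP-4 to 65.8% and the reverse share to 33.0%, the share of 24 h peaks in the 1.5 h list to 20.0%, and the shares in either ESC list to 22.7% (1.5 h) and 70.0% (24 h). Regions in all 4 lists became 1. Extension by 1 kb gave 63.9% and 44.3% between the ESC lists, and 41.3% (1.5 h) and 36.8% (24 h) in either ESC list. Lists of equal length gave 48.5% and 49.5% between the ESC lists, 12.0% of 1.5 h peaks in the 24 h list, 10.2% (1.5 h) and 1.50% (24 h) in either ESC list, and 1 region in all 4. With only the ESD-EpiSC list limited to scores of at least 100, the shares in either ESC list were 36.4% (16 of 44) at 1.5 h and 70.0% (7 of 10) at 24 h, so the lower 1.5 h share went with the shorter ESC lists and the higher 24 h share with the shorter 24 h list. For the other shares the cause was not tested. Placement near peaks (within 50 kb, of the lists named in the methods) lowered the ratio to chance to 25.8 and 26.2 between the ESC lists, and to 19.6 (1.5 h) and 16.0 (24 h) in ESCs. Without peaks of 80 bp or less, a setting added after the data were seen, 36.2% of 24 h peaks lay in an ESC list. Within tertiles of peak width, the probability that a shared peak scored higher was 0.672 in LIF+serum and 0.699 in LIF+BMP-4. For 1.5 h peaks shared with ESCs it turned to 0.467, from a value whose interval already held 0.5; the cause was not tested. Overlap of 50% of the shorter peak left the share between the ESC lists, the share of ESD-EpiSC peaks in either ESC list and the number of regions in all 4 lists within their intervals or within 1.5 times. Of the planned settings for the values that answer a comparison, 25 left the value within its limit, 26 moved it past that limit and 1 turned it; of those added later, 16 left it and 1 moved it. The limit was the 95% interval for shares and probabilities, 1.5 times for counts and, for ratios to chance, the interval of the share divided by the placed share. Unknown depth limits every statement about a missing peak.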

Other observations

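Peaks of each list lay closer together than under uniform random placement. Of the gaps between neighbouring peaks, 17.5% in LIF+serum and 23.8% in LIF+BMP-4 were 10 kb or less, against means of 4.20% and 6.30% in 100 random placements. In ESD-EpiSCs the shares were 27 of 205 gaps (13.2%) at 1.5 h and 8 of 112 (7.14%) at 24 h, against means of 0.132% and 0.205%. Any uneven spread of peaks along the chromosomes would give such an excess, so it does not show clustered binding. The ESD-EpiSC lists also hold the chromosome 8 cluster, where read pile-up in repeated sequence was not tested. The most ESC peaks in a 100-kb window were 21, in 6 windows picked after the counts were seen. Among them, chromosome 12 from 88200001 to 88300000 and chromosome 4 from 57800001 to 57900000 each held 11 LIF+BMP-4 and 10 LIF+serum peaks, and chromosome 8 from 114400001 to 114500000 held 16 and 5. Of the 6, only chromosome 6 from 136400001 to 136500000, with 13 and 8 ESC peaks, also held an ESD-EpiSC peak, 1 at 24 h.

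The tests of the chromosome 8 share and of the narrow peaks were chosen after those results were seen, and those of peak width in LIF+serum before. The chromosome 8 share at 1.5 h stayed above both ESC shares without narrow peaks (15.0%, 10.3 to 20.9). It also did so without the cluster from 19720076 to 20019922 (12.8%, 8.67 to 17.9). These intervals treat peaks as independent, which they are not, and narrow peaks and cluster were not removed together. Their part in the 1.5 h excess is therefore not settled. At 24 h the shares were 9.57% (4.47 to 17.4) and 11.2% (6.26 to 18.1), intervals that hold both ESC shares, so either could account for the excess there. An extra copy of chromosome 8 in the ESD-EpiSC culture is a hypothesis that cannot be told apart from binding at particular places: by equal parts of the chromosome, the ratio of 1.5 h to LIF+BMP-4 peak share was 1.99 (0.961 to 3.58), 2.96 (1.71 to 4.70) and 1.19 (0.519 to 2.31), and the first was 0.828 (0.227 to 2.09) outside the cluster. A difference in binding between the primed and naive states stays open and was not tested.

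Narrow ESD-EpiSC peaks met ESC peaks less often than their widths and chromosomes together predicted. From the overlap of wider peaks and the random placements of both, 29.3% of narrow peaks would meet an ESC peak, against 4 of 71 observed (5.63%, 1.56 to 13.8). The prediction does not separate width from chromosome, and 17 of the 71 lay on chromosome X. The width limit was chosen on these same peaks, and the interval treats them as independent, so the gap describes these peaks only. On chromosome 8 from 19720076 to 20019922 there were 14 ESD-EpiSC peaks, 10 of them narrow, beside 6 ESC peaks, and 1 of the 14 met an ESC peak. Sequence was not examined, so read pile-up in repeated sequence and binding specific to the primed state both stay open as untested.

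LIF+serum peaks were wider than LIF+BMP-4 peaks at the same places. Merging of neighbours that were each called in LIF+BMP-4 does not account for it. In 5330 pairs that overlapped each other and no other peak, the median width ratio was 1.48 (1.47 to 1.50). Merging with a neighbour that was not called in LIF+BMP-4 would still give such a pair and was not tested. A property of the whole library, such as fragment length or caller settings, may account for it: LIF+serum peaks were the wider ones in 89.1% of pairs in the lowest quintile of LIF+serum score and 94.9% in the highest. The lowest value falls just short of the 90% set beforehand, so that test leaves this open. Medium and library cannot be separated with 1 library each, and an effect of the medium was not tested.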
